A study of Homo sapiens with 36 samples.

How the data were processed

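RNA of THP-1 cells was extracted and purified, per the labels, with Trizol followed by an RNeasy column and DNase, its quality was read on a Bioanalyser, and biotinylated cRNA was hybridised to Illumina HumanHT-12 v4 bead arrays. There were 36 arrays, 3 biological replicates for each of 12 groups. The deposited non-normalized table gave, per the file headers, an average bead intensity and a detection p-value for each of 47222 probes on each array, with 72 further columns of bead numbers and bead standard errors that were not used here. The authors also deposited a value table, per array, on a log2 scale. Its values equalled the log2 of the raw intensity after quantile normalisation to within 0.00079, and each of its 36 columns correlated best with its own raw column. The submitters' text names GeneSpring GX. The slide of each array was read from the array names in the file headers and written as slide 1, 2 or 3.

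The raw intensities were background-corrected, quantile-normalised and log2-transformed with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the background estimated from the detection p-values. A probe was kept where its detection p was under 0.05 on at least 3 arrays (26473 probes). Gene symbols came from the platform annotation, brought up to date by gene ID from a RefSeq gene table used for names alone (30073 probes matched). Probes with 1 symbol numbered 30112, with several 8 and with none 17102; the last 2 kinds were left out. Each gene took its probe with the highest mean, which gave 13582 genes, of which 3777 had more than 1 detected probe. No coordinates were used, and the genome build was not given in the sources used here. CCL4 was not among the genes tested. GNB5 had probes called in both directions for LPS against control at 4 h. Signals near background limit fold changes: where the dim group was not above background, the fold is written as a lower limit.

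A linear model with 1 mean per group was fitted to all 36 arrays with limma's lmFit and eBayes, and 21 contrasts were tested: 14 between 2 groups and 7 interactions. Calls are at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. All tests were two-sided. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1, which is why the pooled model was used. Before the data were examined, 34 gene lists, the contrasts, the alternatives and the rule for named genes were written down. The rule named, per comparison, the 10 largest rises and 10 largest falls among called genes whose replicates did not overlap, up to 4 called members per list, and 15 fixed genes; interactions took 5 and 5, and a comparison with fewer than 5 calls the 5 smallest p-values. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 34 lists of a contrast, and again with an estimated correlation. Members were also counted with p adjusted over the list alone.

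Replicate numbers were checked for pairing by correlating the deviations of arrays of the same number from their group means. At 4 h all 7 comparisons passed the criterion of 0.1 (correlations 0.123 to 0.7), and at 24 h 2 of 7 (0.00598 to 0.384), so counts with the replicates as a block are given beside the result for paired comparisons where they moved the count more than 1.5 times. This block took a number as shared by both times. Across the times, however, arrays of the same number had a median correlation of 0.0519, and of different numbers −0.0245. Counts with the block within each time are given with the processing alternatives, and they were larger for the SB comparisons. All arrays of a group shared a slide, so slide was entered as a block in a model with stimulus, SB and time, all their two-way interactions and no three-way interaction. In 3 interactions an additive slide effect cancels.

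The test was tried on simulated data made from these arrays. Of genes changed 1.5-fold in gp120 against control at 4 h 12% were recovered, of those changed 2-fold 64%, 3-fold 94% and 4-fold 98%, with 7.59% false calls; for the LPS by SB interaction at 4 h the figures were 0%, 30%, 84% and 80%, with 3.96% false calls. With no change put in, at most 1 gene was called over the 21 contrasts and 4.62% to 5.36% of p-values fell under 0.05. The simulated arrays were drawn independently, without the pairing of replicate numbers seen at 4 h. In LPS against control at 24 h a shifted list of 40 genes was found by camera at the preset correlation with p = 1.3e-37, and 3 of 100 unshifted lists fell under the threshold.

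The alternatives were no background correction, scaling of arrays to equal medians, the authors' log2 values, no detection filter, a detection p under 0.01, all detected probes, the mean of a gene's probes, the replicates as a block, only the groups compared in the fit, an intensity trend with robust variances, slide as a block, and leaving out each array in turn. Added after seeing the data were the replicates as a block within each time and a fit without the 6 arrays numbered 1 at 4 h. In judging an alternative, a count within 1.5 times the reported one and a gene uncalled in both fits were taken as unchanged, and a called value as turned when its sign changed.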

Results

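Gene expression was measured in the human monocytic leukaemia cell line THP-1 on Illumina HumanHT-12 v4 bead arrays. The cells received HIV-1 envelope protein gp120 (strain SF162, 1 nM), bacterial lipopolysaccharide (LPS, 1 µg/ml) or neither, with or without a 15 min pretreatment with SB203580 (SB, 10 µM), an inhibitor of the kinase p38 MAPK. RNA was taken after 4 h and after 24 h. The 12 groups were control, gp120, LPS, SB, SB+gp120 and SB+LPS at each time, with 3 biological replicates each, 36 arrays in all. The array held 47222 probes, and 13582 genes were tested. The comparisons addressed how gp120 and LPS change transcription in monocytic cells, and how much of each response depends on p38.

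The mean raw signal per array ran from 403.38 to 1571.8, and 34.8% to 44.38% of the probes were detected. Correlations between replicates ran from 0.965 to 0.994. The dimmest arrays were replicate 1 of LPS at 4 h (mean signal 456.7) and replicate 1 of SB+LPS at 4 h (403.38), and both stood apart on the first principal component, which held 32.8% of the variance. The arrays lay on 3 slides with 12 arrays each. Slide 1 held control, gp120, LPS and SB of 24 h. Slide 2 held SB+gp120 and SB+LPS of 24 h with control and gp120 of 4 h. Slide 3 held LPS, SB, SB+gp120 and SB+LPS of 4 h. All replicates of a group were therefore on 1 slide, so that 7 of the 14 comparisons of 2 groups were made within a slide and 7 between slides. For the latter, values are also given from a model with slide as a block, which needs the SB effect on a stimulus to be equal at both times and has larger standard errors (median 0.461 in place of 0.23 for LPS against control at 4 h).

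All changes are differences of log2 intensity with the SE of the limma fit, n = 3 arrays per group throughout, and adjusted p-values from that fit. These p-values rest on the spread within groups pooled over all 36 arrays, and not on the 3 replicates of the groups compared alone. Gene lists and the rule that picked the named genes were set before the data were examined. In each comparison the rule took the largest rises and falls only where 3 arrays of a group were all above the 3 of the other group. Chance gives this for 10% of genes, and since the rule required it, it adds no support to the genes named. The number of arrays per group limits the precision.

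**Figure D1:**
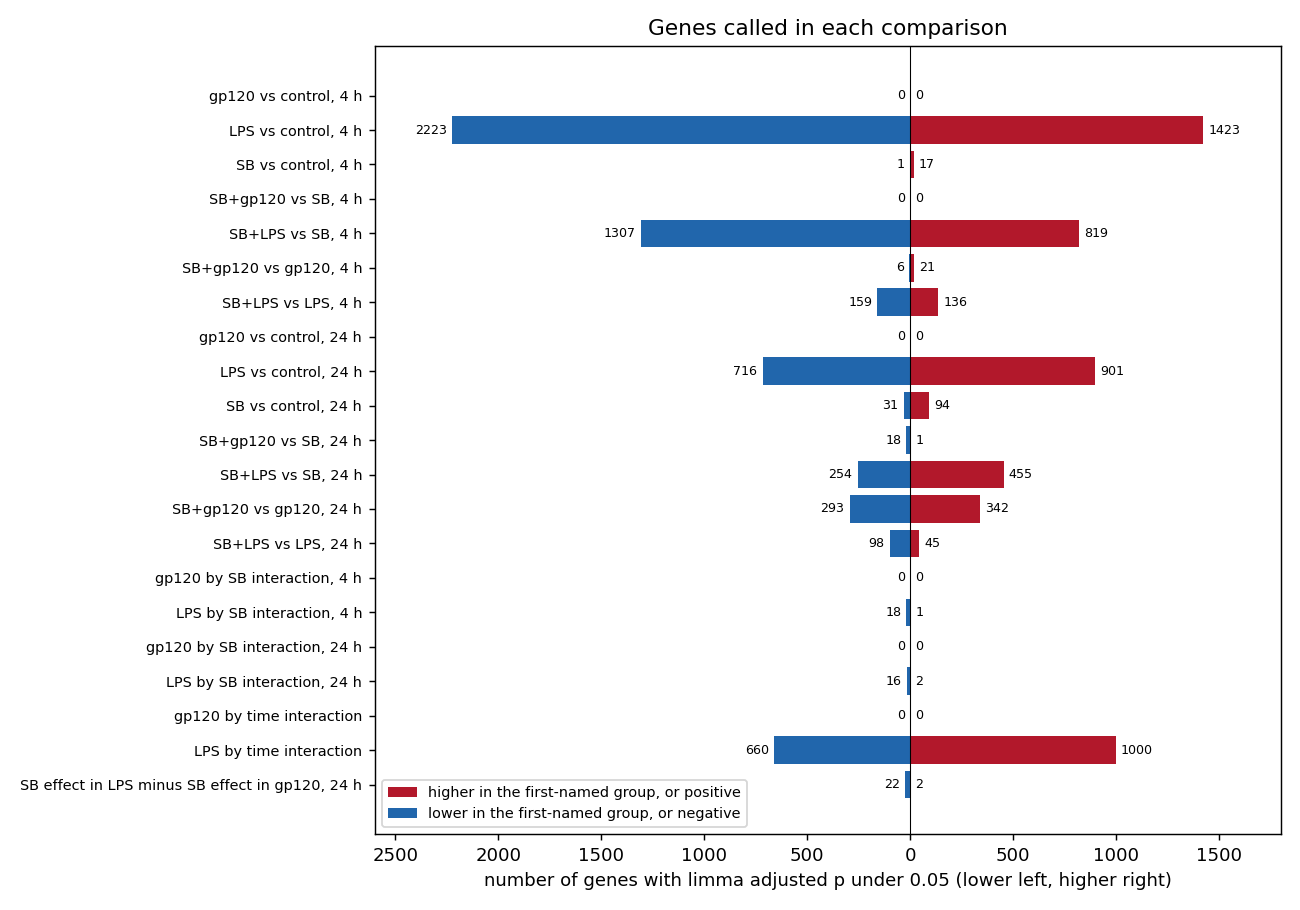
Number of genes called higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 in each of the 21 contrasts, n = 3 arrays per group. LPS against control at 4 h had the most, 1423 higher and 2223 lower, while gp120 against control had 0 at either time.

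LPS for 4 h raised genes of the acute inflammatory response in THP-1 cells. CCL4L1, a macrophage inflammatory protein whose signal cannot be parted with certainty from that of its paralog, rose by 7.90 (SE 0.395, adjusted p = 2.01e-15). EBI3, a subunit of the IL-12 family cytokines IL-27 and IL-35, rose by 7.39 (SE 0.362, adjusted p = 1.44e-15). The neutrophil chemoattractant CXCL8 rose by 7.10 (SE 0.397, adjusted p = 2.62e-14) and CCL20 by 7.05 (SE 0.445, adjusted p = 4.52e-13). The pyrogenic cytokine IL1B rose by 6.41 (SE 0.533, adjusted p = 1.55e-10), TNF by 3.54 (SE 0.412, adjusted p = 1.4e-07), and the interferon-inducible chemokine CXCL10 by 5.74 (SE 0.262, adjusted p = 5.13e-16). The prostaglandin synthase PTGS2 rose by 2.27. IL10, an anti-inflammatory cytokine, had a difference of −0.01 (adjusted p = 0.987). Among the falls were the monocyte chemokine receptor CCR2, −3.19 (SE 0.371, adjusted p = 1.43e-07), and the lipid-presenting molecule CD1D, −2.94 (SE 0.251, adjusted p = 2.87e-10).

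The lists moved together at 4 h of LPS. Of 23 genes of the NF-kB family and its feedback, 21 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 3.02 and an adjusted list p of 3.76e-33. Examples were the kinase IRAK2 at 5.45, the adhesion molecule ICAM1 at 5.06 and NFKB2 at 4.53. Of 19 chemokines, 16 rose and 0 fell (16 and 0 over the list alone; median 2.41, adjusted p = 2.45e-19). Of 16 pro-inflammatory cytokines, 9 rose (10 rose and 1 fell over the list alone; median 1.96, adjusted p = 1.13e-10), among them IL23A at 6.32. Of 22 mRNAs with AU-rich elements, sequences through which p38 signalling stabilises transcripts, 14 rose and 0 fell (median 2.29, adjusted p = 1.04e-17). Of 42 interferon-stimulated genes, 32 rose and 0 fell, the same counts as over the list alone (median 1.57, adjusted p = 1.11e-17, but adjusted p = 0.0731 with an estimated correlation). Examples were MX2 at 3.39 and IFIT1 at 3.21. Feedback genes of the dual-specificity phosphatase and Sprouty families (9 of 19 rose, 1 fell; median 0.828, adjusted p = 0.000682) and genes of apoptosis and survival (9 of 21 rose, 1 fell; median 0.565, adjusted p = 0.000682) were also higher relative to other genes. The latter included BCL2A1, an antiapoptotic BCL2 relative, at 4.39. In the AP-1 and EGR immediate-early list 8 of 21 rose and 1 fell (median 0.537, adjusted p = 6.41e-05), with JUN at 3.05. In the list of the kynurenine pathway, NADPH oxidase and glutamate handling 5 of 18 rose and 2 fell (median 0.613, adjusted p = 0.00126), with GCH1 at 3.43 and KYNU at 1.95.

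In all, 3646 genes were called between LPS and control at 4 h, 1423 higher and 2223 lower, and 1502 changed at least 2-fold. LPS was on slide 3 and control on slide 2. A fit with slide as a block called 428 genes, 294 higher and 134 lower, with values of 10.22 for CCL4L1, 8.97 for EBI3, 8.86 for CXCL8, 7.48 for CCL20, 8.02 for IL1B, 4.03 for TNF, 6.64 for CXCL10, 2.93 for PTGS2, −2.94 for CCR2 and −2.11 for CD1D, and list medians of 2.77 for NF-kB, 2.13 for chemokines, 2.14 for cytokines, 2.37 for AU-rich mRNAs, 1.15 for dual-specificity phosphatases, 0.89 for AP-1 and EGR genes, 0.32 for the kynurenine list and 1.64 for interferon-stimulated genes. The apoptosis list had a median of −0.07 in that fit. Without LPS replicate 1 the count was 2087. Scaling the arrays to equal medians in place of quantile normalisation moved the median of all genes by −0.71 and the share of higher calls from 39% to 8.35%, and the medians of the AP-1 and EGR, apoptosis and MHC class II lists to −0.07, −0.27 and −0.28. The balance of rises and falls in this comparison therefore depends on the scaling. Some called rises had negative values with equal medians, such as CD4 at −0.22 and CD74 at −0.28, neither called there. The rises of the inflammatory lists did not change direction with it.

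LPS for 24 h kept cytokine and chemokine genes high and added genes of the differentiated macrophage. The monocyte chemoattractant CCL2 rose by 7.90 (SE 0.709, adjusted p = 1.17e-09), at least 128-fold since control lay at background. The matrix metalloproteinase MMP9 rose by 7.49 (SE 0.399, adjusted p = 1.93e-14), at least 95.3-fold. EBI3 rose by 7.40 (SE 0.362), IL1B by 6.79 (SE 0.533), CXCL8 by 6.48 (SE 0.397), TNF by 3.40 (SE 0.412) and PTGS2 by 1.59 (SE 0.315, adjusted p = 0.000552). The LPS co-receptor CD14 rose by 5.76 (SE 0.535, adjusted p = 2.31e-09), the endosomal RNA sensor TLR8 by 4.53 (SE 0.259, adjusted p = 7.48e-14) and osteopontin, SPP1, by 5.95 (SE 0.486). Telomerase reverse transcriptase, TERT, fell by 3.16 (SE 0.572, adjusted p = 0.000172), and the neutrophil granule proteases PRTN3 and CTSG fell by 3.13 (SE 0.706) and 2.04 (SE 0.165).

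Of the 42 interferon-stimulated genes 38 rose at 24 h and 0 fell (40 and 0 over the list alone; median 2.45, adjusted p = 1.97e-58), with IFI27 at 5.35, IFI44 at 5.25 and IFIT1 at 4.98. Chemokines (13 of 19 rose, 1 fell; 15 and 1 over the list alone; median 2.73, adjusted p = 3.38e-20), NF-kB genes (17 of 23 rose; median 1.91, adjusted p = 2.09e-25), cytokines (8 of 16 rose; median 1.37, adjusted p = 1.93e-10) and AU-rich mRNAs (16 of 22 rose, 1 fell; median 1.85, adjusted p = 1.14e-19) stayed high. Of 27 genes of macrophage differentiation and scavenger receptors 12 rose and 0 fell (15 and 0 over the list alone; median 0.785, adjusted p = 2.75e-13), with CD36 at 2.46. In the Toll-like receptor list 11 of 24 rose (14 rose and 1 fell over the list alone; median 0.697, adjusted p = 3.53e-10), with LY96, the MD-2 partner of TLR4, at 4.18. In the MHC class II and costimulation list 7 of 11 rose (10 over the list alone; median 0.786, adjusted p = 6.19e-09), with CD86 at 2.13. Of 12 HIV-1 entry and chemokine receptors 4 rose and 0 fell (5 and 0 over the list alone; median 0.57, adjusted p = 0.00155, but adjusted p = 0.0582 with an estimated correlation). CD4, the HIV-1 receptor, had a difference of 0.22 (adjusted p = 0.651) and the coreceptor CXCR4 of 0.11 (adjusted p = 0.937). Markers of the granulocyte lineage fell: 6 of 9 were lower (median −0.97, adjusted p = 1.66e-05). All 12 arrays of these groups and of gp120 and SB lay on slide 1. The test called 1617 genes, 901 higher and 716 lower, and 1038 without LPS replicate 1. With arrays scaled to equal medians 692 genes were called, and the share of higher calls moved from 55.7% to 76.3%.

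The LPS response itself differed between the times. The test of LPS by time called 1660 genes, 1000 with a higher LPS difference at 24 h and 660 with a lower one. MMP9 had a difference between times of 7.30 (SE 0.564, adjusted p = 2.37e-10), an estimate that rests on signal at background in control and in LPS at 4 h. The difference was 5.72 for CD14 (SE 0.757) and 4.98 for TLR8 (SE 0.366, adjusted p = 7.76e-11). SGPP2, a sphingosine phosphatase, had −4.34 (SE 0.318, adjusted p = 7.76e-11), and CCN2, a matricellular growth factor, −4.41 (SE 0.496). Interferon-stimulated genes were higher at 24 h (18 of 42 called higher, median 1.10, adjusted p = 1.71e-09, but adjusted p = 0.318 with an estimated correlation). NF-kB genes were lower at 24 h (11 of 23 called lower, median −1.05, adjusted p = 3.21e-07, but adjusted p = 0.185 with an estimated correlation). A fit with slide as a block called 116 genes, 48 higher and 68 lower, with MMP9 at 4.74, CD14 at 3.10 (adjusted p = 0.187), TLR8 at 3.15, SGPP2 at −3.53 and CCN2 at −2.12 (adjusted p = 0.165), and the list medians were 1.01 for interferon-stimulated and −1.18 for NF-kB genes. With arrays scaled to equal medians the all-gene median moved by 0.64 and the share of higher calls from 60.2% to 91.6%.

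SB added to LPS for 4 h was compared with LPS within slide 3. THBS1, thrombospondin 1, was lower in SB+LPS than in LPS by −4.17 (SE 0.277, adjusted p = 2.72e-11), at least 9.88-fold. EID3 was lower by −2.97 (SE 0.254, adjusted p = 5.51e-09), the oxidised LDL receptor OLR1 by −2.51 (SE 0.258, adjusted p = 3.43e-07) and the eosinophil chemoattractant CCL24 by −1.99 (SE 0.302, adjusted p = 0.000377). TNFSF10, the death ligand TRAIL, was lower by −2.50 (SE 0.431, adjusted p = 0.00145). LFNG, a Notch-modifying glycosyltransferase, was higher by 2.03 (SE 0.266, adjusted p = 2.98e-05), PHLDA2 by 1.79 (SE 0.238, adjusted p = 3.13e-05) and the immediate-early transcription factor EGR1 by 1.86 (SE 0.382, adjusted p = 0.00816).

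The main inflammatory cytokines did not pass the test between SB+LPS and LPS at 4 h. That test does not use the pairing of replicate numbers seen at 4 h. TNF differed by 0.97 (SE 0.412, adjusted p = 0.241), IL1B by 0.48 (SE 0.533, adjusted p = 0.758), CXCL8 by −0.07 (SE 0.397, adjusted p = 0.972) and PTGS2 by −0.15 (adjusted p = 0.901). By replicate number IL1B was 15.07, 14.17 and 14.72 in LPS and 15.48, 14.8 and 15.12 in SB+LPS, higher with SB in each. IL6 fell by 1.45 (SE 0.351, adjusted p = 0.0251), a call that ended without LPS replicate 1 (−0.97), LPS replicate 2 (−1.44), SB+LPS replicate 1 (−1.17) or SB+LPS replicate 3 (−1.48). CXCL10 fell by 1.08 (SE 0.262, adjusted p = 0.0251), a call that ended without LPS replicate 1 (−1.13), LPS replicate 2 (−0.93) or SB+LPS replicate 1 (−0.81). The EGR1 call ended without SB+LPS replicate 3 (1.37). Of the 42 interferon-stimulated genes 2 fell, and 17 fell when adjusted over the list alone (median −0.72, adjusted p = 3.44e-11, but adjusted p = 0.681 with an estimated correlation). Chemokines (3 of 19 fell, median −0.08, adjusted p = 0.033) and NRF2 targets (0 of 13 called, 4 lower over the list alone, median −0.43, adjusted p = 1.69e-05) were lower, with adjusted p = 0.749 and adjusted p = 0.261 with an estimated correlation. Genes of the unfolded protein and amino acid stress response were higher (1 of 21 rose, 2 over the list alone; median 0.23, adjusted p = 0.033, but adjusted p = 0.681 with an estimated correlation), with a median of −0.02 under equal medians. The AU-rich mRNAs (0 rose and 2 of 22 fell; median −0.03, adjusted p = 0.423) and the cytokine list (0 rose and 1 of 16 fell; median 0.10, adjusted p = 0.841) were not called.

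In total 295 genes were called between SB+LPS and LPS at 4 h, 136 higher and 159 lower, and 581 with the replicates as a block. The count depended on single arrays. It was 101 without LPS replicate 1, 186 without SB+LPS replicate 3, 56 without the 6 arrays numbered 1 at 4 h, and 0 when only the 6 arrays of the comparison entered the fit, where THBS1 had an adjusted p of 0.115. Equal medians left 29 calls, shifted the all-gene median by −0.19 and moved the share of higher calls from 46.1% to 6.9%; the TNFSF10 and EGR1 calls ended there, at −2.22 and 1.61.

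**Figure D2:**
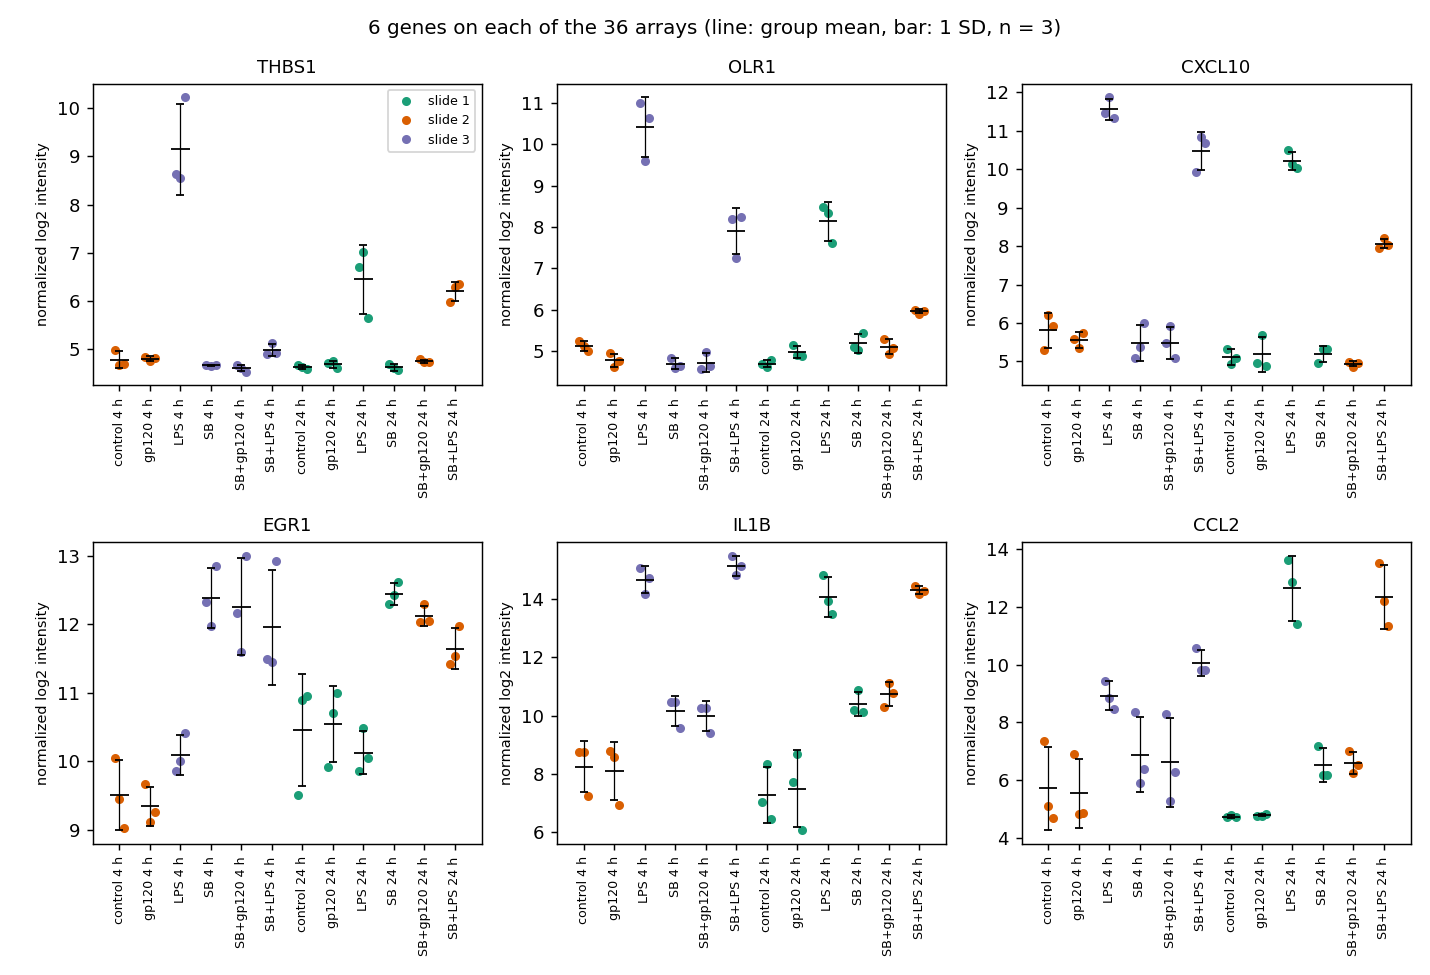
Log2 intensity of THBS1, OLR1, CXCL10, EGR1, IL1B and CCL2 on each array, by group and time, coloured by slide; points are arrays and bars the mean and SD of 3 replicates. THBS1 was −4.17 lower in SB+LPS than in LPS at 4 h, while IL1B differed by 0.48 between these groups.

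At 24 h genes lower in SB+LPS than in LPS included OLR1, CXCL10 and CCL22, which were also called lower at 4 h, and others called at 24 h alone. CXCL13, a B-cell chemoattractant, fell by 2.41 between SB+LPS and LPS (SE 0.209, adjusted p = 2.36e-08). CXCL10 fell by 2.16 (SE 0.262, adjusted p = 8.72e-06), OLR1 by 2.17 (SE 0.258, adjusted p = 6.46e-06), CCL22 by 2.76 (SE 0.496, adjusted p = 0.0021), the tryptophan dioxygenase TDO2 by 2.25 (SE 0.374, adjusted p = 0.000903) and complement C3 by 1.79 (SE 0.282, adjusted p = 0.000513). The interferon-induced GTPase GBP1 fell by 1.61 (SE 0.256, adjusted p = 0.000513). The epithelial membrane protein EMP1 rose by 2.17 (SE 0.445, adjusted p = 0.0085), a call that ended without LPS replicate 1 (1.95) or SB+LPS replicate 3 (2.03). TNF differed by 0.97 (adjusted p = 0.392), IL1B by 0.22 (adjusted p = 0.975) and CXCL8 by −0.49.

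Of the 42 interferon-stimulated genes 5 fell between SB+LPS and LPS at 24 h, and 32 over the list alone (median −0.90, adjusted p = 2.49e-30, but adjusted p = 0.0612 with an estimated correlation). Equal medians ended all 5 calls and brought the list median to −0.27 (adjusted p = 0.431 with an estimated correlation). The adjusted p with an estimated correlation was 0.0224 without background correction, 0.0237 with the authors' values and 0.00635 with the replicates as a block. In the MHC class II and costimulation list 2 of 11 fell (4 over the list alone; median −0.49, adjusted p = 2.64e-07), which held with an estimated correlation (adjusted p = 0.0195), although the median was 0.15 and that adjusted p 0.646 when arrays were scaled to equal medians. The chemokine list was lower (2 of 19 fell, 1 rose and 3 fell over the list alone; median −0.30, adjusted p = 0.00665), but adjusted p = 0.396 with an estimated correlation, and its median was 0.15 with equal medians. The pro-inflammatory cytokine list was the only list called higher (0 of 16 called, median 0.23, adjusted p = 0.0201, but adjusted p = 0.189 with an estimated correlation). SB+LPS lay on slide 2 and LPS on slide 1. The fit called 143 genes, 45 higher and 98 lower, and 31 of the 98 were low in every group on slide 2, again a set defined in part by this difference. With slide as a block limma called 0 genes, with CXCL13 at −2.37, CXCL10 at −1.58, OLR1 at −1.43, CCL22 at −1.69, TDO2 at −2.33, C3 at −2.01, GBP1 at −1.45, EMP1 at 2.24 and a median SE of 0.515, and the lists stood at −1.01 for interferon-stimulated genes (adjusted p = 4.53e-12), −0.19 for chemokines (adjusted p = 0.463) and −0.59 for MHC class II (adjusted p = 0.000862). The count was 69 without LPS replicate 1, 87 without SB+LPS replicate 1, 74 without SB+LPS replicate 2 and 74 without SB+LPS replicate 3. Equal medians moved the all-gene median by 0.53 and the share of higher calls from 31.5% to 77.8%.

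Whether SB changed the LPS difference itself was tested as an interaction. At 4 h 19 genes were called, 1 higher and 18 lower. They included THBS1 at −4.05 (SE 0.391, adjusted p = 3.23e-07), EID3 at −2.80 (SE 0.359, adjusted p = 5.21e-05), OLR1 at −2.08 (SE 0.365, adjusted p = 0.00913), and TP53TG1 at 1.48 (SE 0.289, adjusted p = 0.0198). THBS1 was at background in control and SB+LPS, and OLR1 in control and SB, so these estimates rest in part on undetected signal. Of the 18 lower, 7 were low in every group on slide 2, where only the control of this contrast lay, a set defined in part by the same values. With slide as a block 1 gene was called, with THBS1 at −0.39, EID3 at −0.10, TP53TG1 at 0.28 and OLR1 at −1.92; the LPS by SB term of that model covers both times. At 24 h 18 genes were called, 2 higher and 16 lower, with CXCL13 at −2.59 (SE 0.295, adjusted p = 1.34e-05), OLR1 at −2.66 (SE 0.365, adjusted p = 0.00029) and SLAMF8, a receptor of myeloid cells, at −2.88 (SE 0.474, adjusted p = 0.00263). With slide as a block 1 gene was called, and CXCL13 stood at −2.54 (adjusted p = 0.0156), OLR1 at −1.92 and SLAMF8 at −3.12. The count at 4 h was 9 without control replicate 1, 12 without control replicate 2, 11 without LPS replicate 3, 12 without SB replicate 2 and 9 without SB replicate 3. The count at 24 h was 36 without LPS replicate 3, 11 without SB+LPS replicate 2 and 11 without SB+LPS replicate 3, and equal medians moved the share of higher calls from 11.1% to 0% and the all-gene median by 0.27. Interferon-stimulated genes had a median interaction of −0.57 at 4 h (0 of 42 called, adjusted p = 1.65e-05) and −0.77 at 24 h (0 called, 4 over the list alone, adjusted p = 2.91e-16), with adjusted p = 0.714 and adjusted p = 0.108 with an estimated correlation, and −0.84 in the fit with slide as a block. The chemokine median at 24 h was −0.94 (1 of 19 called lower, adjusted p = 2.62e-10, but adjusted p = 0.0564 with an estimated correlation).

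In cells that had received SB, LPS still raised cytokine, chemokine and NF-kB genes. At 4 h, within slide 3, SB+LPS against SB called 2126 genes, 819 higher and 1307 lower. CCL20 rose by 7.13 (SE 0.445), EBI3 by 6.82 (SE 0.362), CXCL8 by 6.49 (SE 0.397, adjusted p = 3.29e-13), IL1B by 4.97 (SE 0.533, adjusted p = 4.42e-08) and TNF by 3.33 (SE 0.412, adjusted p = 5.86e-07), while IL6 had 0.71 (SE 0.351, adjusted p = 0.177). Of 23 NF-kB genes 21 rose (median 2.53, adjusted p = 5.7e-40), of 16 cytokines 9 (median 1.5, adjusted p = 1.77e-13), of 19 chemokines 10 (median 0.86, adjusted p = 1.32e-18) and of 42 interferon-stimulated genes 22 (24 over the list alone; median 0.92, adjusted p = 9.24e-13, but adjusted p = 0.157 with an estimated correlation). Of the 1423 genes called higher by LPS without SB at 4 h, 630 were also called higher here, where independent calls would share 85.8. Without SB+LPS replicate 1 the count was 1237, and with equal medians it was 4807, with 5.43% higher in place of 38.5% and an all-gene median of −0.66.

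At 24 h SB+LPS against SB called 709 genes, 455 higher and 254 lower. EBI3 rose by 5.97 (SE 0.362, adjusted p = 2.64e-12), MMP9 by 5.47 (SE 0.399, adjusted p = 1.11e-10), CXCL8 by 4.78 (SE 0.397) and the interferon-induced synthetase OAS3 by 3.82 (SE 0.299, adjusted p = 3.06e-10). Of 42 interferon-stimulated genes 36 rose (38 over the list alone; median 1.68, adjusted p = 1.2e-53), of 16 cytokines 9 (median 1.25, adjusted p = 3.88e-16), of 19 chemokines 10 rose and 1 fell (median 1.67, adjusted p = 1.14e-15) and of 23 NF-kB genes 15 rose (median 1.34, adjusted p = 1.76e-23). Granulocyte-lineage markers fell (3 of 9, 5 over the list alone; median −0.74, adjusted p = 1.86e-05; −1.02 and adjusted p = 0.00703 with slide as a block). Here SB+LPS was on slide 2 and SB on slide 1. Fitted with slide as a block, 38 genes were called, 35 higher and 3 lower, with EBI3 at 5.25, MMP9 at 5.05, CXCL8 at 4.11 and OAS3 at 3.70, and list medians of 1.74, 1.27, 1.72 and 1.36 in the same order. Of the 901 genes called higher by LPS without SB at 24 h, 406 were also called higher here, where independent calls would share 30.2. With equal medians the all-gene median moved by 0.19 and the share of higher calls from 64.2% to 82.2%.

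SB without a stimulus had 18 genes called at 4 h, between slides, and 125 at 24 h, within a slide. Whether its effect differs between the times was not tested. At 4 h EGR1 was higher by 2.88 (SE 0.382, adjusted p = 0.000274) and 1.89 with slide as a block (adjusted p = 0.566). TNF had a difference of 1.18 (adjusted p = 0.47) and IL1B of 1.92 (adjusted p = 0.24), in the fit that does not use the pairing at 4 h. By replicate number IL1B was 8.749, 8.747 and 7.249 in control and 10.46, 10.47 and 9.575 in SB, on different slides. Dual-specificity phosphatase and Sprouty genes were higher as a list (0 of 19 called, median 0.26, adjusted p = 0.00865, but adjusted p = 0.33 with an estimated correlation; median 0.78 and adjusted p = 0.0101 with slide as a block). In all 18 genes were called, 17 higher and 1 lower, 32 with the replicates as a block, and 8 with slide as a block, 4 higher and 4 lower. Of the 18, 10 were low in every group on slide 2, where the control lay, though this set is defined in part by the same difference. The count was 7, 10 and 8 without control replicates 1, 2 and 3 and 7, 10 and 5 without SB replicates 1, 2 and 3, and the all-gene median moved by −0.31 with equal medians.

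At 24 h, within slide 1, SB raised EMP1 by 3.92 (SE 0.445, adjusted p = 4.09e-06), IL1B by 3.10 (SE 0.533, adjusted p = 0.00164), the stress cytokine GDF15 by 2.97 (SE 0.455, adjusted p = 0.000476), the protease inhibitor A2M by 2.89 (SE 0.451, adjusted p = 0.000533) and PHLDA1 by 2.69 (SE 0.328, adjusted p = 1.43e-05). CCL5 rose by 1.25 (SE 0.246, adjusted p = 0.0058) and the glucose transporter SLC2A3 by 1.58 (SE 0.255, adjusted p = 0.00082). EGR1 rose by 1.99 (SE 0.382, adjusted p = 0.00454), a call that ended without control replicate 1 (1.52). Coagulation factor F13A1 fell by 2.09 (SE 0.382, adjusted p = 0.00297; −1.70 and adjusted p = 0.0502 without control replicate 1), and the mTOR-binding protein DEPTOR fell by 1.66 (SE 0.268, adjusted p = 0.000784), a call that ended with equal medians. TNF had 1.58 (adjusted p = 0.0602). Dual-specificity phosphatase and Sprouty genes, with 2 of 19 rising (7 over the list alone; median 0.54, adjusted p = 1.03e-08), AP-1 and EGR genes, with 2 of 21 rising (6 over the list alone; median 0.57, adjusted p = 2.5e-07), and macrophage genes, with 3 of 27 rising (8 over the list alone; median 0.49, adjusted p = 5.73e-08), held with an estimated correlation (adjusted p = 0.00212, 0.0205 and 0.0468). Apoptosis and survival genes were higher as a list (1 of 21 rose; median 0.14, adjusted p = 0.0176, adjusted p = 0.0468 with an estimated correlation, but 0.0852 without background correction). Granulocyte-lineage markers were lower as a list (0 of 9 called, 1 higher and 3 lower over the list alone; median −0.53, adjusted p = 0.00155, adjusted p = 0.0188 with an estimated correlation). With equal medians none of these lists held with an estimated correlation (adjusted p = 0.176 for phosphatases, AP-1 and EGR genes and granulocyte markers, 0.343 for macrophage and 0.796 for apoptosis genes). Chemokines (3 of 19 rose, 7 over the list alone; median 0.26, adjusted p = 0.000117) and cytokines (2 of 16 rose, 3 over the list alone; median 0.22, adjusted p = 0.00155) did not, with adjusted p = 0.206 and adjusted p = 0.0804 with an estimated correlation. Nor did AU-rich mRNAs (2 of 22 rose, 6 over the list alone, median 0.265, adjusted p = 5.08e-05, and 0.0991 with an estimated correlation). The same held for NF-kB genes (2 of 23 rose, 6 over the list alone, median 0.199, adjusted p = 0.000478, and 0.283). NRF2 targets and glycolysis genes, higher, and LXR targets, lower, were also called at the preset correlation alone (adjusted p = 0.0069, 0.0069 and 0.0426). Interferon-stimulated genes had 0 of 42 called and a median of −0.10 (adjusted p = 0.178). The fit called 125 genes, 94 higher and 31 lower. The count was 58 without control replicate 1, 75 without control replicate 3, 63 without SB replicate 2 and 71 without SB replicate 3, and equal medians moved the all-gene median by 0.22 and the share of higher calls from 75.2% to 98.9%.

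gp120 produced no called gene in THP-1 cells. At 4 h, within slide 2, limma called 0 genes and 259 of 13582 had an unadjusted p under 0.05. That is a smaller share than the 4.62% to 5.36% of the simulation with no change put in, whose arrays were not paired. TNF differed from control by −0.23 (SE 0.412), IL1B by −0.15 (SE 0.533), CXCL8 by −0.44, CXCL10 by −0.25 and CD4 by 0.07. The smallest p belonged to the calcium-binding protein gene CABP7 at −0.72 (SE 0.191, adjusted p = 1). At 24 h, within slide 1, limma called 0 genes and 409 had an unadjusted p under 0.05; TNF differed by −0.16, IL1B by 0.22, CCL3 by 0.39 and CD4 by 0.21. The smallest p belonged to the phosphatase subunit PPP2R5B at 1.03 (SE 0.242, adjusted p = 0.999). None of the 34 lists was called at either time: cytokines had a median of 0.03 at 4 h and 0.05 at 24 h, chemokines of −0.17 and 0.06, interferon-stimulated genes of 0.01 and 0.03, and HIV-1 entry and chemokine receptors of −0.07 and −0.01. In simulated data of this size 12% of genes changed 1.5-fold and 64% of genes changed 2-fold were recovered in the 4 h comparison, so most changes of 1.5-fold in single genes would be missed there. The gp120 by time test called 0 genes in limma, with 345 at an unadjusted p under 0.05. Equal medians moved the all-gene median of gp120 against control by −0.22 at 4 h and by 0.25 at 24 h, and of gp120 by time by 0.47.

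**Figure D3:**
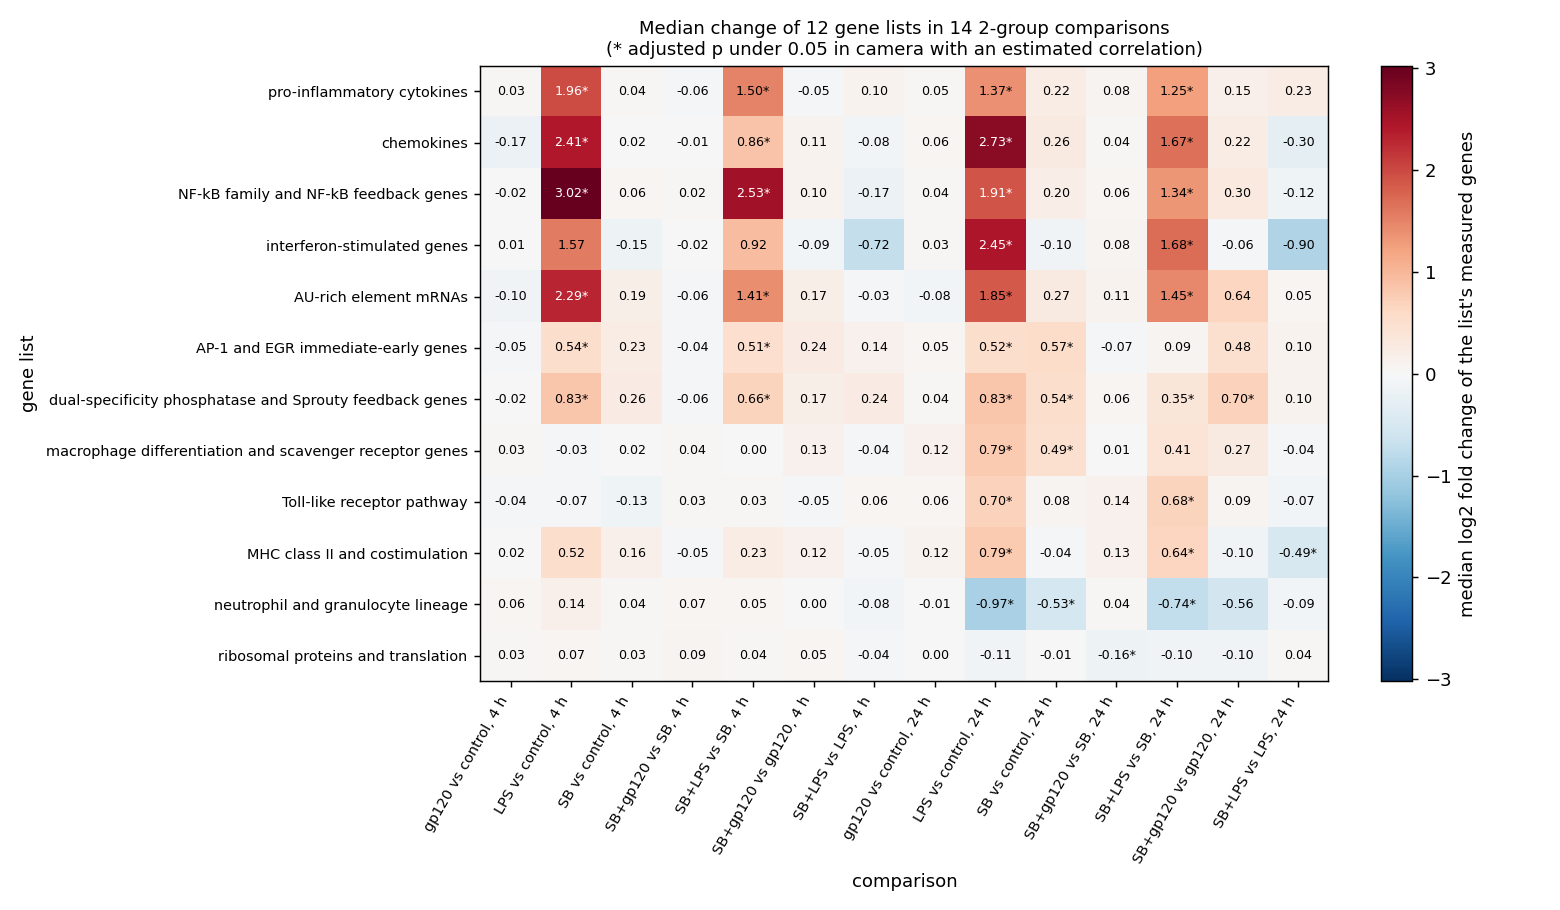
Median log2 difference of 12 gene lists (vertical) in the 14 comparisons of 2 groups (horizontal), as colour; an asterisk marks an adjusted p under 0.05 with an estimated correlation. The NF-kB list had a median of 3.02 for LPS against control at 4 h and 1.91 at 24 h, and no list was marked for gp120 against control.

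gp120 on top of SB was compared with SB. At 4 h, within slide 3, limma called 0 genes, with 542 at an unadjusted p under 0.05. RASA2 had the smallest p, at −1.51 (SE 0.324, adjusted p = 0.839), and it alone was called without SB+gp120 replicate 1 (−1.92). At 24 h 19 genes were called, 1 higher and 18 lower. The antisense RNA EZR-AS1 fell by 1.74 (SE 0.221, adjusted p = 0.000122), LINC01102 by 1.63 and DPP10, a potassium channel subunit gene, by 1.19 (SE 0.222, adjusted p = 0.0138). SB+gp120 was on slide 2 and SB on slide 1, and with slide as a block limma called 0 genes, with EZR-AS1 at 0.26, LINC01102 at 0.04 and DPP10 at 0.27. The count was 3 without SB+gp120 replicate 2, 4 without SB+gp120 replicate 3, 12 without SB replicate 1, 7 without SB replicate 2 and 9 without SB replicate 3. Ribosomal protein genes were the only list called (0 of 18 called, median −0.16, adjusted p = 0.0135), and their median was 0.02 with slide as a block and 0.02 with equal medians. The gp120 by SB test called 0 genes in limma at 4 h (181 at an unadjusted p under 0.05) and 0 at 24 h (623), where 3 were called without gp120 replicate 3 and 1 without SB replicate 3. Equal medians moved the all-gene median by −0.16 for SB+gp120 against SB at 4 h and by −0.15 for gp120 by SB at 24 h.

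**Figure D4:**
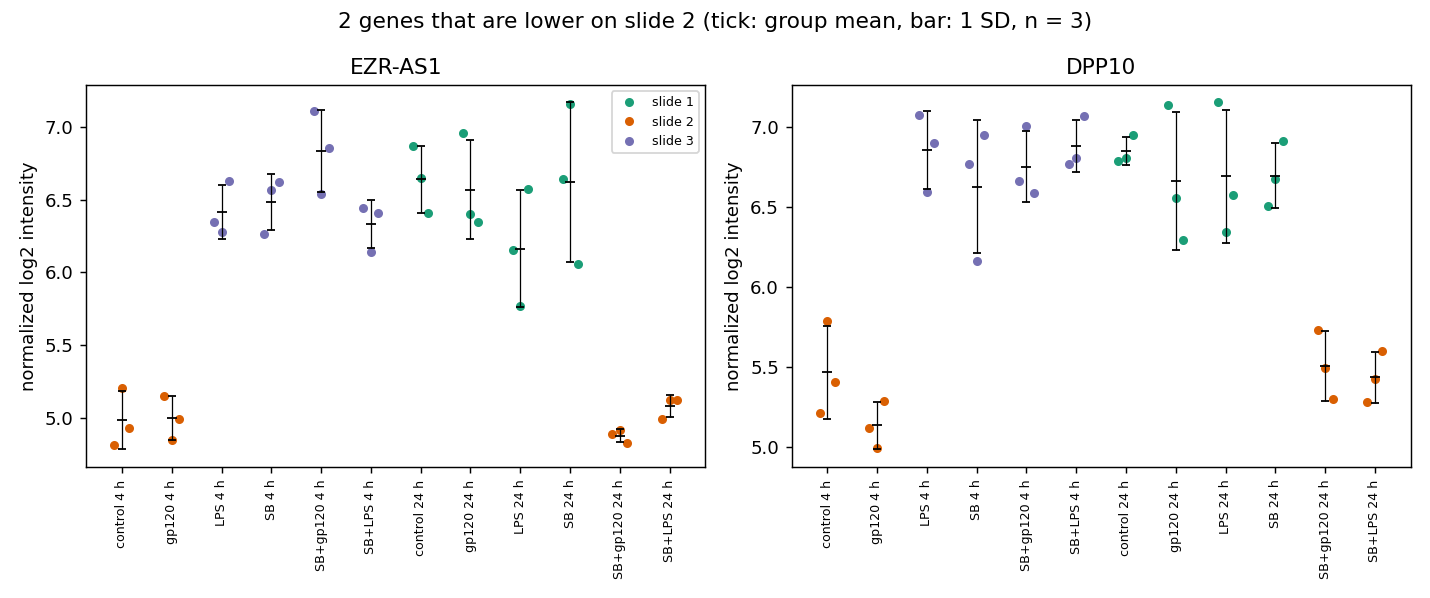
Log2 intensity of EZR-AS1 and DPP10 on each of the 36 arrays, by group, coloured by slide; points are arrays. Arrays on slide 2 lie lowest in both treated and control groups; EZR-AS1 differed by −1.74 between SB+gp120 and SB at 24 h.

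The effect of SB in cells given gp120 was tested between SB+gp120 and gp120. At 4 h EGR1 rose by 2.91 (SE 0.382, adjusted p = 8.66e-05; 1.92 and adjusted p = 0.202 with slide as a block), and the fatty acid receptor GPR84 by 1.86 (SE 0.335, adjusted p = 0.00606; 2.41 and adjusted p = 0.0543 with slide as a block; 1.74 and not called without gp120 replicate 3). The fit called 27 genes, 21 higher and 6 lower, 45 with the replicates as a block and 46 with slide as a block, 34 higher and 12 lower. Of the 21 higher, 11 were low in every group on slide 2, where gp120 lay, though this set is defined in part by the same difference. Among these 11 was EZR-AS1 at 1.84, which stood at −0.70 with slide as a block. The count was 17 without gp120 replicate 2, 13 without gp120 replicate 3, 49 without SB+gp120 replicate 1 and 14 without SB+gp120 replicate 3, and equal medians moved the all-gene median by −0.24.

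At 24 h SB+gp120 against gp120 raised EMP1 by 3.86 (SE 0.445, adjusted p = 5.77e-06), A2M by 3.37 (SE 0.451, adjusted p = 2.92e-05), IL1B by 3.23 (SE 0.533, adjusted p = 0.000544), CXCL8 by 1.94 (SE 0.397, adjusted p = 0.00467) and PHLDA1 by 2.59, and lowered F13A1 by −2.28 (SE 0.382, adjusted p = 0.000715). TNF rose by 1.83 (SE 0.412, adjusted p = 0.0101), a call that ended without gp120 replicate 2 (1.60) or SB+gp120 replicate 3 (1.56). The list of dual-specificity phosphatases and Sprouty genes was higher (5 of 19 rose, 8 rose and 1 fell over the list alone; median 0.70, adjusted p = 1.63e-05, adjusted p = 0.0317 with an estimated correlation, but 0.315 under equal medians), and AU-rich mRNAs too (6 of 22 rose, 10 over the list alone; median 0.64, adjusted p = 1.63e-05, but adjusted p = 0.169 with an estimated correlation). Granulocyte-lineage markers fell (2 of 9, 3 over the list alone; median −0.56, adjusted p = 0.00939, but adjusted p = 0.0551 with an estimated correlation; −0.57 and adjusted p = 0.0552 with slide as a block). The groups were on slides 2 and 1. The fit called 635 genes, 342 higher and 293 lower; with slide as a block limma called 0, with a median SE of 0.399, EMP1 at 3.92 (adjusted p = 0.0627), A2M at 2.68, IL1B at 3.06, CXCL8 at 1.28, PHLDA1 at 2.94, TNF at 1.74 and F13A1 at −1.78, and list medians of 0.42 and 0.15. The count was 192 without gp120 replicate 2, 972 without gp120 replicate 3 and 170 without SB+gp120 replicate 3. Equal medians moved the share of higher calls from 53.9% to 75.8%. Of the 94 genes higher in SB than in control at 24 h, 76 were also called higher here, on other arrays, where independent calls would share 2.37.

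The SB effect at 24 h was compared between LPS and gp120, a contrast in which an additive slide effect cancels. It called 24 genes, 2 higher and 22 lower: CXCL13 had −2.67 (SE 0.295, adjusted p = 7.22e-06), SLAMF8 −2.99 (SE 0.474, adjusted p = 0.00143) and the growth factor carrier IGFBP3 −2.67 (SE 0.493, adjusted p = 0.0106; −2.44 and not called without SB+LPS replicate 3). The count was 14 without gp120 replicate 1, 14 without LPS replicate 1, 46 without LPS replicate 3, 14 without SB+gp120 replicate 3, 13 without SB+LPS replicate 2 and 11 without SB+LPS replicate 3, and equal medians moved the all-gene median by 0.41. Interferon-stimulated genes had a median of −0.77 (0 of 42 called, 6 over the list alone; adjusted p = 1.47e-14, but adjusted p = 0.161 with an estimated correlation) and chemokines of −0.79 (1 of 19 called lower, 3 over the list alone; adjusted p = 2.44e-07, but adjusted p = 0.134 with an estimated correlation).

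The genes induced by LPS at one time were followed in the SB comparison of the other. The 901 genes that rose with LPS at 24 h had a median of −0.03 in SB+LPS against LPS at 4 h, −0.04 relative to all other genes (camera at the preset correlation, p = 0.187), with 34 called lower and 23 higher. The 1423 genes that rose with LPS at 4 h had a median of −0.07 in SB+LPS against LPS at 24 h, −0.10 relative to other genes (camera, p = 5.4e-05, but p = 0.183 with an estimated correlation), with 42 called lower and 6 higher.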

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

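The splits and reassignments of arrays were fixed before the values were known, while the tests of slide, of gp120, of LPS carry-over and of SB itself were chosen only after the results were seen.

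The genes lower in SB+gp120 than in SB at 24 h (18 genes, median −1.21) have slide as a candidate explanation. On arrays outside the comparison, control and gp120 of 4 h on slide 2 lay −1.13 below control and gp120 of 24 h on slide 1 for these genes, with 18 of 18 lower, while the median of all genes was −0.01. Against slide 3 the median was −0.82, with 17 of 18 lower. An effect of gp120 in SB-treated cells is not needed for the low values, since SB+LPS on the same slide, without gp120, was about as low (difference −0.13). These genes had a median of 5.05 on slide 2, near background, so a further fall with gp120 could not be seen there. Within slide 3 at 4 h the difference of gp120 in cells with SB was −0.05. Without SB, gp120 against control at 24 h had −0.20.

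The lower interferon-stimulated genes in SB+LPS than in LPS at 24 h could come from slide, or from SB acting on the LPS response. The mean of the list was −0.95 (SE 0.263), with 41 of 42 genes lower. In the contrast where an additive slide effect cancels it was −0.88 (SE 0.372), with 38 of 42 lower, which argues against slide. Within slide 3 at 4 h it was −0.71 (SE 0.263), with 39 of 42 lower, and the replicate differences were −0.75, −0.72 and −0.66. In the main fit, camera with an estimated correlation called the list in none of these contrasts (adjusted p = 0.0612 for SB+LPS against LPS at 24 h). In that comparison the same test called it without background correction (adjusted p = 0.0224), with the authors' values (0.0237) and with the replicates as a block (0.00635). Equal medians brought its median in that comparison from −0.90 to −0.27. That SB limits the interferon part of the LPS response remains a hypothesis. Its direct test, the LPS by SB interaction of the list, was not called with an estimated correlation at 4 h or at 24 h. In gp120-treated cells the list had −0.07 (SE 0.263).

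The 94 genes higher in SB than in control at 24 h could come from LPS carried into the SB cultures or from SB itself. The interferon-stimulated genes had a mean of −0.14 (SE 0.263) in SB, where their ratio to the cytokine list in LPS without SB would give 0.77. LPS carried over would however act in cells with SB. In SB+LPS against SB the means were 1.94 for interferon-stimulated genes and 1.7 for cytokines at 24 h, and 0.94 and 2.21 at 4 h. The ratio to use is therefore not known, so this test does not exclude carry-over. The rise was also seen on other arrays, as 76 of the 94 genes were also called higher in SB+gp120 than in gp120. Those cultures received SB too, so LPS carried in with it could recur there. This count therefore cannot tell SB itself from carry-over. Of the 94, 61 were also called higher with LPS at 24 h, 30 were not called and 3 were lower. LPS and SB shared their control arrays there, and how much of this overlap the shared arrays give is left open.

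In the LPS by SB test at 4 h 19 genes and 5 lists were called, and 4 of 100 reassignments of arrays, the real one included, gave as many genes, the highest other giving 407. These reassignments did not keep the replicate numbers together, which pair at 4 h. Its largest differences in each direction were TP53TG1 at 1.48, THBS1 at −4.05, EID3 at −2.80, LOC105371763 at −2.50, OLR1 at −2.08 and CEMIP at −1.98. Of these, LOC105371763 was low in every group on slide 2, where the control lay (mean 5.22 there and 6.59 on the other slides). In the LPS by SB test at 24 h 18 genes and 16 lists were called, and 1 of 100 reassignments gave as many, the highest other giving 1. Its largest differences in each direction were MAP4K1 at 1.45, LINC02213 at 1.10, SLAMF8 at −2.88, IGFBP3 at −2.87, OLR1 at −2.66, TDO2 at −2.63 and CXCL13 at −2.59.

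In the LPS by time test 1660 genes and 8 lists were called, and 2 of 100 reassignments gave as many, the highest other giving 1902. Its largest differences in each direction were MMP9 at 7.30, CD14 at 5.72, SPP1 at 5.33, S100A12 at 4.98, TLR8 at 4.98, BAIAP2L1 at −4.67, DNAAF1 at −4.46, CCN2 at −4.41, ATP1B1 at −4.38 and SGPP2 at −4.34. In the SB effect with LPS minus the SB effect with gp120 at 24 h 24 genes and 15 lists were called, and 1 of 100 reassignments gave as many, the highest other giving 3. Its largest differences in each direction were F13A1 at 2.46, MAP4K1 at 1.43, SLAMF8 at −2.99, TDO2 at −2.73, CXCL13 at −2.67, IGFBP3 at −2.67 and PLXDC2 at −2.47.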

How the results depend on the processing

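The settings below were fixed before the data were examined, save the last 2 named, which were tests chosen only after the results were seen. The counts of SB comparisons changed with scaling, with the replicates as a block, with the arrays that enter the fit and with slide, and the cause was not tested.

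Without background correction the count was 9 for SB against control at 4 h, 11 for SB+gp120 against SB at 24 h and 5 for LPS by SB at 4 h, and with the authors' values it was 9, 11 and 5. With the stricter detection filter SB+gp120 against SB at 24 h had 9 and LPS by SB at 4 h 8. With all detected probes SB against control at 4 h had 38, SB+gp120 against gp120 at 4 h 43, SB+gp120 against SB at 24 h 39 and gp120 by SB at 24 h 1.

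With median scaling LPS against control had 6482 at 4 h and 692 at 24 h, SB against control at 4 h 6, SB+LPS against SB at 4 h 4807, SB+gp120 against gp120 8 at 4 h and 124 at 24 h, SB+LPS against LPS at 4 h 29, LPS by SB 5 at 4 h and 4 at 24 h, and the SB effect in LPS minus that in gp120 2. Genes that turned under it for LPS at 4 h were CD4 at −0.22, MT1X at −0.22, CD74 at −0.28, RPS9 at −0.0885 and GUSB at −0.53, and for SB+LPS against SB at 4 h MT1H at −0.15. LPS-induced genes of 24 h stood at −0.077 in SB+LPS against LPS at 4 h under it, and between −0.118 and 0.0342 with single arrays left out. LPS-induced genes of 4 h stood at −0.10 at 24 h with an estimated correlation (p = 0.183), and between −0.154 and −0.0417 with single arrays left out, the latter without LPS replicate 1 of 24 h.

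With the replicates as a block the count was 32 for SB at 4 h, 271 for SB at 24 h, 45 and 1144 for SB+gp120 against gp120 at 4 h and 24 h, 581 and 266 for SB+LPS against LPS, 60 for LPS by SB at 24 h and 77 for the SB effect in LPS minus that in gp120. With only the groups compared in the fit it was 2030 for LPS at 4 h, 6 and 252 for SB at 4 h and 24 h, 762 and 1505 for SB+LPS against SB, 0 and 71 for SB+gp120 against gp120, 0 for SB+LPS against LPS at 4 h, 0 for SB+gp120 against SB at 24 h, 2 and 30 for LPS by SB and 14 for the SB effect in LPS minus that in gp120.

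With slide as a block LPS at 4 h had 428, SB at 4 h 8, SB+gp120 against gp120 46 at 4 h and 0 at 24 h, SB+gp120 against SB at 24 h 0, SB+LPS against SB at 24 h 38, SB+LPS against LPS at 24 h 0, LPS by SB 1 at 4 h and 1 at 24 h and LPS by time 116. Genes that turned, none of them called there, were CD4 at −0.21, SMPDL3A at 0.69, PCNA at 0.10, CD36 at 0.59, TLR1 at 0.33, BCL2L11 at −0.49 and RPS9 at −0.24 for LPS at 4 h, EZR-AS1 at −1.03 and HHATL at −0.27 for SB at 4 h, EZR-AS1 at −0.70 and TTC22 at 0.53 for SB+gp120 against gp120 at 4 h, and EZR-AS1 at 0.31, MIIP at 0.0936 and CA12 at −0.27 at 24 h. For SB+gp120 against SB at 24 h they were BCORL1 at −0.23, EZR-AS1 at 0.26, LINC01102 at 0.0442, KCNQ1OT1 at 0.35, CHRNB4 at 0.0511, LINC02693 at 0.0767 and DPP10 at 0.27, and for LPS by SB at 4 h CEMIP at 0.46.

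Leaving out single arrays gave 2087 to 3796 for LPS at 4 h, 1038 to 1630 for LPS at 24 h, 5 to 10 for SB at 4 h, 58 to 97 for SB at 24 h, 1237 to 2242 for SB+LPS against SB at 4 h, 13 to 49 and 170 to 972 for SB+gp120 against gp120 at 4 h and 24 h, 101 to 404 and 69 to 129 for SB+LPS against LPS, 0 to 1 and 3 to 16 for SB+gp120 against SB, 0 to 3 for gp120 by SB at 24 h, 9 to 26 and 11 to 36 for LPS by SB, and 11 to 46 for the SB effect in LPS minus that in gp120.

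With the replicates as a block within each time the count was 61 and 481 for SB at 4 h and 24 h, 2706 for LPS at 24 h, 3290 and 1360 for SB+LPS against SB, 104 and 1681 for SB+gp120 against gp120, 960 and 444 for SB+LPS against LPS, 36 and 111 for LPS by SB, 2782 for LPS by time and 197 for the SB effect in LPS minus that in gp120. Without the 6 arrays numbered 1 at 4 h it was 2301 for LPS, 8 for SB, 1321 for SB+LPS against SB, 73 for SB+gp120 against gp120, 56 for SB+LPS against LPS and 6 for LPS by SB.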

Other observations

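The lists not described above were tested in LPS against control. At 24 h genes of the inflammasome (6 of 16 rose and 0 fell, 10 over the list alone; median 0.71, adjusted p = 1.7e-06), among them CASP5, an inflammatory caspase, at 3.19, aryl hydrocarbon receptor targets (6 of 11 rose; median 0.77, adjusted p = 0.000453), with CYP1B1 at 2.49, glycolysis and hypoxia-response genes (2 of 22 rose, 4 over the list alone; median 0.46, adjusted p = 2.97e-05) and MHC class I and immunoproteasome genes (4 of 17 rose, 8 over the list alone; median 0.41, adjusted p = 0.00173) were higher. Matrix proteases and the plasminogen system had 7 of 19 rising and 1 falling (10 and 1 over the list alone; median 0.62, adjusted p = 2.43e-06). Eicosanoid synthesis and receptors were higher (5 of 21 rose, 1 fell; median 0.13, adjusted p = 0.0272, but adjusted p = 0.0858 with an estimated correlation), as were anti-inflammatory and cytokine-signal feedback genes (5 of 14 rose, 2 fell; median 0.55, adjusted p = 0.00166, but adjusted p = 0.0858 with an estimated correlation). AP-1 and EGR genes (6 of 21 rose, 1 fell; median 0.52, adjusted p = 0.000109), dual-specificity phosphatase and Sprouty genes (9 of 19 rose; median 0.83, adjusted p = 2.8e-08), apoptosis and survival genes (6 of 21 rose, 1 fell; median 0.43, adjusted p = 0.00575) and the kynurenine, NADPH oxidase and glutamate list (6 of 18 rose; median 0.50, adjusted p = 1.42e-05) were higher at 24 h too. So were NRF2 targets (3 of 13 rose; median 0.46, adjusted p = 0.000109, but adjusted p = 0.0695 with an estimated correlation). Cell cycle genes were lower (0 of 34 called; median −0.38, adjusted p = 0.0485, but adjusted p = 0.654 with an estimated correlation). Metallothioneins, which bind zinc and copper, were higher at 4 h (2 of 6 rose, 4 over the list alone; median 0.60, adjusted p = 0.0092, but adjusted p = 0.298 with an estimated correlation; −0.25 with arrays scaled to equal medians), with MT2A at 3.02; at 24 h 1 of 6 rose (median 0.12, adjusted p = 0.128).

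The other lists were not called for LPS at 24 h. The p38 MAPK pathway components had 2 of 25 rising and 1 falling (median −0.03, adjusted p = 0.609), sterol synthesis and uptake 0 of 20 called (median 0.10, adjusted p = 0.234), LXR targets 2 of 12 rising and 2 falling (median −0.37, adjusted p = 0.67) and the unfolded protein and amino acid stress response 1 of 21 rising and 3 falling (median −0.18, adjusted p = 0.246). Heat shock proteins had 0 of 15 called (median 0.28, adjusted p = 0.115), ribosomal proteins 0 of 18 (median −0.11, adjusted p = 0.185) and housekeeping genes 0 of 13 (median −0.06, adjusted p = 0.864). Markers of T and NK lymphocytes had 1 of 7 rising (median 0.07, adjusted p = 0.387), of B lymphocytes 0 of 4 (median −0.11, adjusted p = 0.734) and of fibroblast and epithelial cells 0 of 5 (median 0.01, adjusted p = 0.609).

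The splits were fixed before the values were known. A comparison of 2 groups of 3 arrays has 10 splits, too few for a share under 0.05, so that chance cannot be told apart from the treatment by splits alone. A real count of 0 is reached by every split whatever the data. At 4 h 10 of 10 splits gave at least the 0 calls of gp120 against control (highest other 2) and 10 of 10 the 0 of SB+gp120 against SB (highest other 1). LPS against control had 3646 with 1 of 10 splits (highest other 0), SB against control 18 with 1 (highest other 0), SB+LPS against SB 2126 with 1 (highest other 1) and SB+gp120 against gp120 27 with 1 (highest other 0). SB+LPS against LPS had 295 with 2 of 10, and the highest other, 516, put the dim arrays numbered 1 of both groups together; among the 4 splits that part all same-numbered pairs, 1 was as large and the highest other was 2. At 24 h 10 of 10 splits gave at least the 0 calls of gp120 against control (highest other 1). The other comparisons at 24 h had 1 of 10 splits, with 1617 for LPS against control (highest other 1), 125 for SB against control (0), 19 for SB+gp120 against SB (0), 709 for SB+LPS against SB (0), 635 for SB+gp120 against gp120 (1) and 143 for SB+LPS against LPS (10).

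For the cross-time sets 7 of 10 splits gave a shift as large as 0.0383 (highest other 0.179) and 3 of 10 one as large as 0.102 (highest other 0.138). For the interactions with 0 calls every reassignment (100 of 100) gives at least as many whatever the data, so the reassignments test nothing there; the highest other was 1493 for gp120 by SB at 4 h, 18 for gp120 by SB at 24 h and 3 for gp120 by time.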
